A study of Mus musculus with 24 samples.

How the data were processed

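ATAC-seq libraries of B-cell progenitors sorted from the bone marrow of WT and Mki67-/- mice at 3 stages, from pre-pro-B through pro-B to small pre-B, were compared, 4 libraries in each of 6 groups. Per the submitters' processing notes, the authors trimmed reads with Trimmomatic and called peaks with MACS2 on mm10; the authors also name deepTools, DiffBind and DESeq2 there, and give no versions. The deposited files are 1 peak list per library. Per the labels and the narrowPeak format, the authors' score is a whole number equal to 10 times the -log10 q. The deposited fold enrichment is a ratio of the summit over the local background of the same library. The deposited -log10 p and -log10 q measure the same summit against that background. The lowest -log10 q in each list lay at 2 to within rounding, that is a q threshold of 0.01. Fold enrichments and q-values come from separate calls in each library, so they were used only to rank, filter and describe peaks within a list.

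Entries that overlapped or touched within a library were merged to 1 peak on chromosomes 1 to 19 and X. Read totals were not used here. A background coverage per library was recovered from the fold enrichment and p-value of 3000 summits with a -log10 q under 30. For each summit, the pileup was sought for which a Poisson p-value matched the deposited one to within 0.01 on the -log10 scale. That pileup and the fold enrichment give the background, and the most frequent background of a library was taken as its coverage. It lay between 1.86 and 5.3. It stands for depth but is not a read count, so no counting interval is given.

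Comparisons by genotype used the deposited lists, since lists of equal length would remove a global change. Comparisons between stages used the 40000 peaks of each library with the highest -log10 q, since the deposited lists differ in length between stages. Overlapping peaks of the 24 libraries were joined to 159326 regions, of which 117987 had a peak in at least 2 libraries of a group. A library had a region where a peak overlapped it by 1 bp. Genes were the 21627 protein-coding genes of the reference, each with 10 kb on both sides, tested where at least 4 libraries had a peak. The reference gives no strand, so a window of 1 kb on both sides of either gene end stood in for the transcription start, and regions were named by the nearest gene end. All 257 entries of 13 gene lists matched a gene, 1 of them by a synonym. The limits of 6 antigen receptor loci ran from the first to the last annotated segment.

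Tests were two-sided exact permutation tests of the difference in means. Genotype was permuted within stage and stage within genotype. The smallest p is 0.0286 for 4 against 4 libraries, 0.000408 for 8 against 8 and 5.83e-06 for 12 against 12. Adjusted p-values follow Benjamini and Hochberg with a threshold of 0.05 within each family of regions, genes, lists or loci. Regions with a peak in all 4 libraries of a genotype and none of the other were counted and set against all 35 splits of the 8 libraries of a stage. Other counts were set against 100 splits drawn with a fixed seed, the real one included. The exact p-values were checked on 200 simulated vectors against full enumeration and differed by at most 2.2e-16.

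The tests were also run on simulated data. Gene counts were drawn from Poisson distributions around the observed means, with changed genes raised to a mean of at least 2 peaks. The shares called therefore do not hold for genes with fewer peaks. For genes between pre-pro-B and pro-B, 200 changed genes of 16213 gave 0 calls at fold changes of 2, 3 and 4. With 2000 changed genes, 25.2% were called at a fold change of 2, 74.8% at 3 and 97.1% at 4, with 12 unchanged genes called. For genes by genotype across stages, 200 changed genes of 17594 gave 4.48% at a fold change of 1.5, 28.4% at 2 and 78.8% at 3, with 1 unchanged gene called. For regions by genotype across stages, 200 changed regions of 87694 gave 4.48% when a peak was present with a chance of 0.8 in one genotype and absent with the same chance in the other. The share was 28.4% for a chance of 0.9 and 100% for a chance of 1. For regions between pre-pro-B and pro-B, 200 changed regions of 39250 gave 0 calls. The smallest p of 0.000408 left almost no room for a call there, so this does not measure recovery. With 2000 changed regions, 2.55%, 19.8% and 100% were called at chances of 0.8, 0.9 and 1.

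The groups, the tests behind the report, the gene lists and most alternatives were fixed before the data were examined; most tests that weigh explanations were chosen later. The rule for named genes was also fixed then. It takes Mki67, the 6 antigen receptor loci, and up to 4 members per list and comparison among those past a test, in order of p and then of difference. It takes the 10 genes per direction with the smallest p and then the largest difference for each stage step and for genotype. It takes the 5 regions per direction of highest mean rank for each stage by genotype, and the 5 of smallest p across stages. Alternatives set then were stricter -log10 q thresholds of 5 and 10, lists of 40000 or 20000 peaks, the deposited lists for stages, regions in at least 3 libraries, a larger overlap with the region, and bins of 500 bp. Others were autosomes only, entries not merged, windows at gene ends only, WT libraries only, leaving out each library, and blocks by label number or by file-name number. A fold threshold of 4, sex read from Y-linked genes as a stratum, coverage as a covariate, and leaving out 3 doubted libraries were added after the data were seen. These 3 are Mki67-/- pre-pro-B replicate 4 and Mki67-/- small pre-B replicate 1, of the lowest coverage, and WT small pre-B replicate 1, with narrow peaks and a high share on X. Chromosome Y, the mitochondrial genome and unplaced sequences were left out of the comparisons. Read coverage tracks and differential tables were not analysed here. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.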

Results

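Chromatin accessibility was measured by ATAC-seq, which reads out DNA open to a transposase, in B-cell progenitors of mouse bone marrow sorted at 3 stages, from pre-pro-B through pro-B to small pre-B. Mice were WT or Mki67-/-; Mki67 encodes Ki-67, a nuclear protein of dividing cells. Each of the 6 groups had 4 libraries, each with its own peak list on mm10. The lists held 77044 to 206148 entries, or 54387 to 88946 merged peaks per library. The background coverage recovered from the lists ran from 1.86 to 5.3. Its mean was lower in Mki67-/- than in WT libraries in each stage. It was 3.255 ± 0.987 against 4.29 ± 1.26 in pre-pro-B, 2.92 ± 0.679 against 3.15 ± 0.21 in pro-B and 2.58 ± 0.514 against 3.12 ± 0.595 in small pre-B cells (n = 4 each). The labels do not state whether libraries came from separate mice, so p-values measure the spread between libraries. Libraries of different stages may come from the same mice, in which case p-values across stages may be too small. Fold enrichments and q-values are the authors' own for each library and only rank peaks within a list. Errors are SDs, and tests are two-sided exact permutation tests unless named otherwise.

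Mki67 itself (chromosome 7, 135689784 to 135716450) kept a peak at its boundary of higher coordinate in all 24 libraries. The reference gives no strand, so this boundary may be the transcription start. The part of the peak shared by all libraries ran from 135716337 to 135716829. The peak stood between the top 6.08% and the top 15.6% of each library's list. The locus held 5.5 ± 1.29 peaks in WT and 5.75 ± 1.26 in Mki67-/- pre-pro-B libraries (n = 4 each). It held 2.75 ± 0.5 and 2.75 ± 0.957 in pro-B and 2.25 ± 0.5 and 2.25 ± 0.957 in small pre-B libraries (n = 4 each). Across stages the permutation p was 1. A peak at this site does not check the deletion, whose position the labels do not give.

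The first comparison asks whether the loss of Ki-67 changed accessibility as a whole. WT pre-pro-B cells had 84682 ± 5256 peaks and Mki67-/- ones 80504 ± 9103 (n = 4 each, exact p = 0.571). Pro-B cells had 74698 ± 3669 and 74484 ± 2682 (n = 4 each, exact p = 0.943). Small pre-B cells had 70569 ± 10504 and 65298 ± 7900 (n = 4 each, exact p = 0.543). Peaks covered 49.0 ± 6.66 Mb in WT and 42.8 ± 6.78 Mb in Mki67-/- pre-pro-B cells (n = 4 each). They covered 30.0 ± 1.49 and 30.6 ± 2.40 Mb in pro-B and 26.8 ± 2.65 and 25.8 ± 3.16 Mb in small pre-B cells (n = 4 each). No adjusted p was below 0.714 for either measure. The direction of the difference in peak number was not stable. In pre-pro-B it turned without Mki67-/- replicate 4, the library of lowest coverage in that group (difference 17.3 peaks). In pro-B it turned in 3 of 8 runs without 1 library, and in small pre-B without the 3 doubted libraries. With coverage as a covariate it turned in pre-pro-B and pro-B, to 1461 and 960 peaks. Shares of peaks at gene ends, in gene bodies and between genes also did not pass, with the lowest exact p at 0.429 (n = 4 each).

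The antigen receptor loci are where V(D)J segments are joined, the step that the study's title concerns. Igh, the heavy-chain locus (chromosome 12, 113256204 to 116009954), held more peaks in Mki67-/- than in WT libraries across stages. The means were 159 ± 54.6 and 135 ± 57.7, an SD that includes the stages (n = 12 each, permutation p = 0.0238, adjusted p = 0.0479 over 6 loci). In small pre-B cells, WT libraries had 72.8 ± 10.2 Igh peaks and Mki67-/- libraries 136 ± 43.4 (n = 4 each, exact p = 0.0571, adjusted p = 0.171). In pro-B cells the values were 205 ± 14.7 and 225 ± 10.7, and in pre-pro-B cells 126 ± 4.27 and 118 ± 12.7 (n = 4 each, exact p = 0.143 and 0.257).

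Among the 40000 strongest peaks of each library, Igh held 28 ± 2.45 peaks in WT small pre-B cells (26 to 31) and 48.8 ± 3.59 in Mki67-/- ones (46 to 54). In pro-B cells it held 94.8 ± 5.5 and 109 ± 2.99 (n = 4 each). Both had an exact p of 0.0286, the smallest that 4 against 4 allow, and an adjusted p of 0.171. Across stages these lists gave 52.7 ± 31.6 and 65.4 ± 32.9 (n = 12 each, permutation p = 0.000239, adjusted p = 0.00143). Of 120 Igh V segments, 3.75 ± 0.5 in WT and 10.3 ± 2.06 in Mki67-/- small pre-B libraries had one of these peaks within 500 bp (n = 4 each, exact p = 0.0286, adjusted p = 0.286). In the deposited lists the numbers were 11 ± 1.83 and 37.8 ± 17.2 (n = 4 each, exact p = 0.0286, adjusted p = 0.857). The length of Igh covered by deposited peaks did not pass across stages (adjusted p = 0.219).

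**Figure D1:**
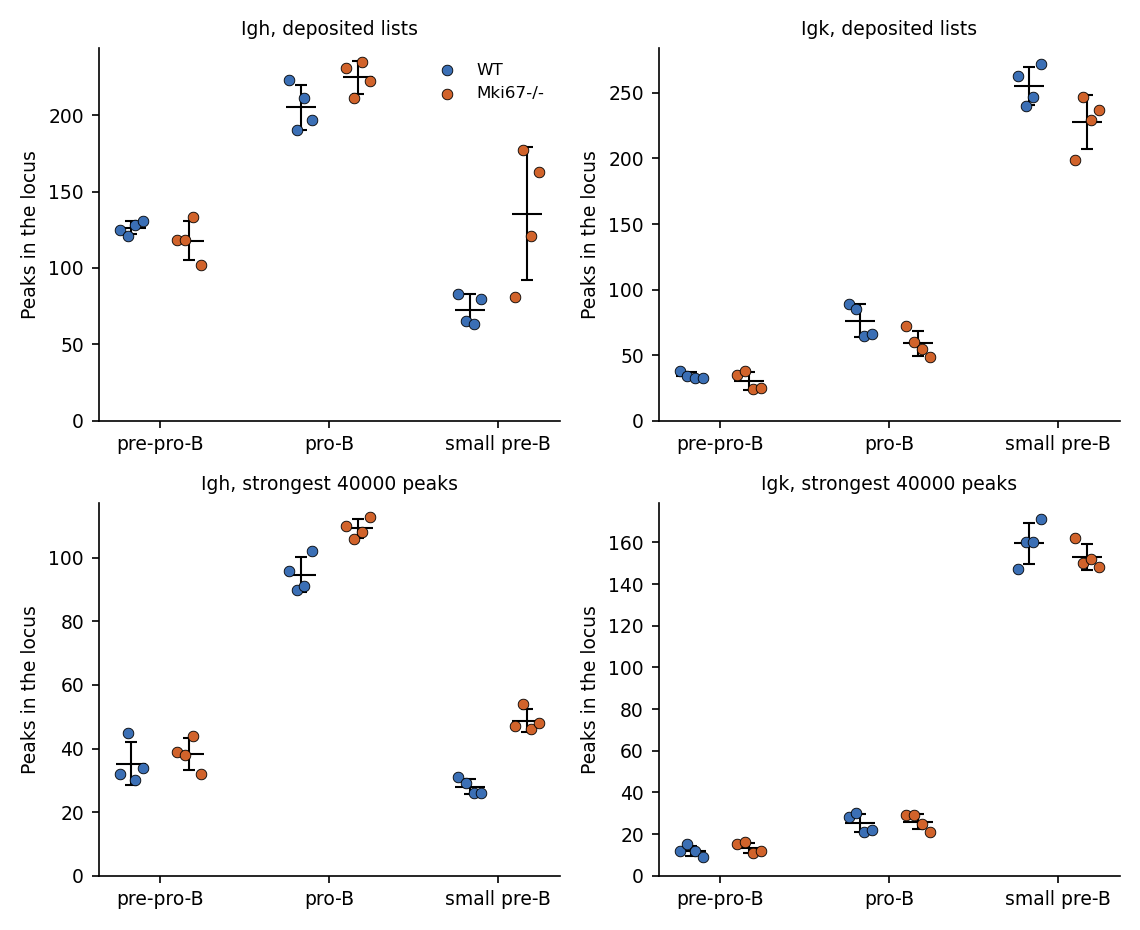
Peaks in Igh and Igk in each library by stage and genotype, from the deposited lists and from the 40000 strongest peaks; points are libraries, bars the mean and SD (n = 4). In the lower left panel, Mki67-/- small pre-B libraries lie at 46 to 54 peaks and WT ones at 26 to 31.

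Igk, the kappa light-chain locus (chromosome 6, 67555636 to 70726754), held 122 ± 101 peaks in WT and 106 ± 91.9 in Mki67-/- libraries across stages (n = 12 each, permutation p = 0.00345, adjusted p = 0.0207). This call was lost with the 40000 strongest peaks, at 65.6 ± 69.8 and 64.2 ± 65.9 (n = 12 each, permutation p = 0.573, adjusted p = 0.657). In those lists, 70.5 ± 1.73 of 102 Igk V segments had a peak in WT and 64.5 ± 1.29 in Mki67-/- small pre-B cells (n = 4 each, exact p = 0.0286, adjusted p = 0.286); in the deposited lists the numbers were 88.3 ± 1.5 and 82.5 ± 3.87 (n = 4 each, exact p = 0.0857, adjusted p = 0.857). Igl, the lambda locus (chromosome 16, 19061752 to 19260844), held 13 ± 4.92 and 12 ± 4.55 peaks (n = 12 each, permutation p = 0.0239, adjusted p = 0.0479); with the 40000 strongest peaks it turned and the call was lost, at 8 ± 3.33 and 8.25 ± 3.47 (n = 12 each, permutation adjusted p = 0.657). By the length covered by deposited peaks neither Igk nor Igl passed across stages (permutation adjusted p = 0.219 for both). The T-cell receptor loci Tcra/Tcrd, Tcrb and Tcrg did not pass in the deposited lists, with adjusted p-values of 0.848, 0.848 and 1. These loci were set beforehand as a comparison, since they are not rearranged in B cells. In the 40000 strongest peaks, Tcra/Tcrd held 16.8 ± 11.4 peaks in WT and 20.2 ± 12.2 in Mki67-/- libraries (n = 12 each, permutation adjusted p = 0.00485). A higher count in these lists was thus not particular to Igh. In pre-pro-B cells Tcra/Tcrd held 31 ± 3.37 and 35.5 ± 3.11, and in pro-B cells 14.5 ± 1 and 17.3 ± 1.89 (n = 4 each, exact p = 0.114 and 0.0857). In small pre-B cells it held 5 ± 0.816 and 7.75 ± 1.71 of these peaks (n = 4 each, exact p = 0.0571, adjusted p = 0.171). In the deposited lists of that stage it held 16 ± 4.97 and 26.3 ± 7.5 (n = 4 each, exact p = 0.0857, adjusted p = 0.171). This has the direction of Igh in that stage, where neither locus passed. For Tcrb and Tcrg the lowest exact p there was 0.229.

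The Igh call in the deposited lists is close to the threshold. It was lost in 16 of 24 runs that left out 1 library (adjusted p of 0.0529 to 0.1), with blocks by label number (0.122), with sex as a stratum (0.066), and at -log10 q thresholds of 5 (0.14) and 10 (0.407). Without 3 doubted libraries (Mki67-/- pre-pro-B replicate 4 and replicate 1 of both small pre-B groups), Igh had an adjusted p of 0.0536 and Igk of 0.0565, and no locus passed.

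The effect of genotype on Igh differed between stages in the deposited lists. The log2 effect was -0.11 in pre-pro-B, 0.13 in pro-B and 0.84 in small pre-B cells. The permutation adjusted p was 0.0453 between pre-pro-B and pro-B, 0.0367 between pre-pro-B and small pre-B, and 0.101 between pro-B and small pre-B. With the 40000 strongest peaks the adjusted p-values were 0.664, 0.0722 and 0.0722. For Igk and for peak number the lowest adjusted p between stages was 0.793.

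**Figure D2:**
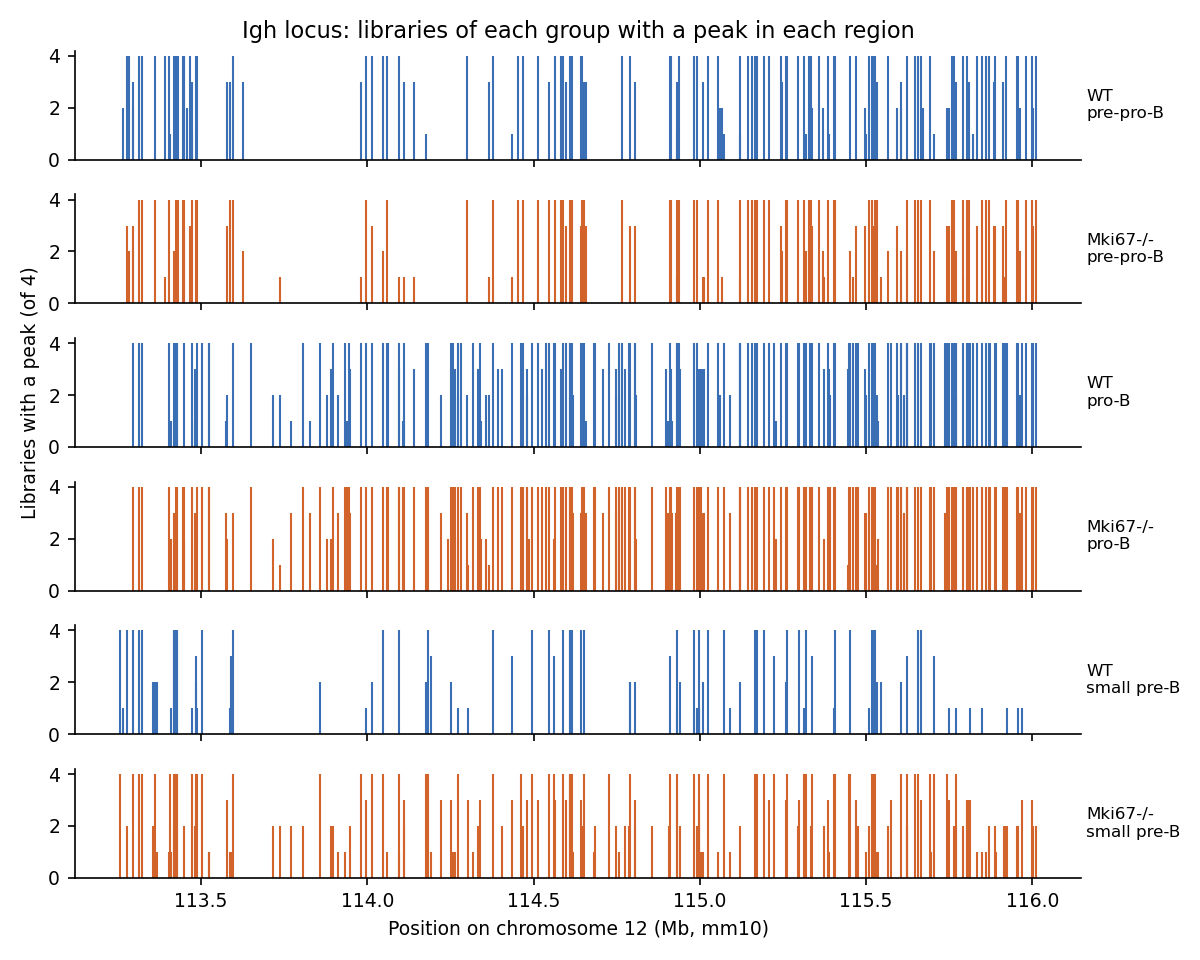
The Igh locus on chromosome 12 (Mb, mm10), with the number of the 4 libraries of each group that have a peak in each region. More regions have a peak in Mki67-/- than in WT small pre-B libraries, as in the mean counts of 136 and 72.8.

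Regions with a peak in all 4 libraries of a genotype and in none of the other were counted within each stage. Pre-pro-B cells had 225 such WT regions and 38 Mki67-/- regions, pro-B cells 272 and 254, and small pre-B cells 333 and 460. The real split of pro-B libraries gave 526 regions against at most 204 in the other splits, and that of small pre-B libraries 793 against at most 291, each 1 of 35 splits. In pre-pro-B cells, 6 of 35 splits gave at least the 263 regions of the real one, with up to 643. Mean coverage was lower in Mki67-/- libraries of this stage, and the counts were not adjusted for it. Of the 460 regions of Mki67-/- small pre-B cells, 415 (90.2%) had a peak in all 4 WT pro-B libraries and 433 (94.1%) in all 4 Mki67-/- pro-B libraries. Among the 34146 regions that varied between small pre-B libraries, 44.0% had a peak in all 4 WT pro-B libraries. Of the 333 WT regions, 39 (11.7%) did. Without any 1 of the 4 WT small pre-B libraries, 2 of 35 splits of the other 7 gave as many. Which genotype had more such regions was not stable in 2 stages. In small pre-B cells WT had more at a -log10 q of at least 10 (301 and 213), where peaks had to cover 0.5 of a region (316 and 291) and in 4 of 8 runs without 1 library (such as 660 and 523 without WT replicate 3). The Mki67-/- count was 1600 of 1970 without Mki67-/- replicate 1. In pro-B cells Mki67-/- libraries had more with the 40000 strongest peaks (170 and 173), with the larger overlap (199 and 272) and in 3 of 8 runs without 1 library. Totals in the order of the stages were 131, 343 and 713 with the 40000 strongest peaks and 55, 246 and 312 with the 20000 strongest. Runs without 1 library, where fewer have to match, gave 389 to 841, 672 to 887 and 993 to 1970, highest without WT pre-pro-B replicate 2 (779 WT and 62 Mki67-/-), WT pro-B replicate 1 and Mki67-/- small pre-B replicate 1.

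**Figure D3:**
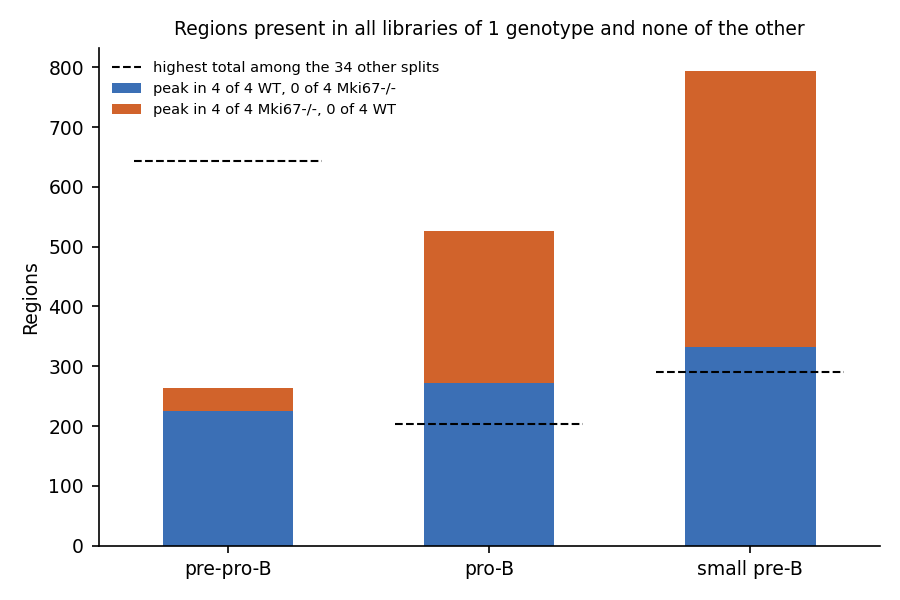
Regions with a peak in all 4 libraries of a genotype and none of the other, stacked by genotype for each stage; dashed lines give the highest total among the other splits of the same 8 libraries. The totals of 526 in pro-B and 793 in small pre-B cells lie above their lines at 204 and 291, and that of 263 in pre-pro-B cells lies below 643.

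The strongest of these regions in WT pre-pro-B cells lay nearest Oxa1l, Cdc42ep3, Hnrnpll, Plpp4 and Lyrm7, and those in Mki67-/- pre-pro-B cells nearest C130074G19Rik, Pwwp2b, Cd81, Htra1 and Wdr11. In pro-B cells they lay nearest Oxa1l, Lyrm7, Jakmip3, Dtx1 and Tcerg1l in WT, and Pwwp2b, Tnip1, 1700056E22Rik, Cttn and Eda2r in Mki67-/- libraries. In small pre-B cells they lay nearest Anxa6, Atox1, Tcerg1l, Sit1 and Zfp827 in WT, and Stk32c, Kcnk15, 1700056E22Rik, Dusp4 and Rad18 in Mki67-/- libraries. Regions within 10 Mb of Mki67, singled out after their values were seen, made up 26 of the 263 in pre-pro-B (9.89%), 29 of the 526 in pro-B (5.51%) and 23 of the 793 in small pre-B cells (2.90%). Among all regions that varied between the libraries of these stages they made up 1.34, 1.40 and 1.27%. Those nearest Pwwp2b, Cd81, Htra1, Wdr11, Plpp4, Jakmip3, Tcerg1l, Cttn and Stk32c lie there. The region nearest Rad18, a ubiquitin ligase gene of DNA damage tolerance, lay 42149 bp from its nearest end and inside no gene (chromosome 6, 112576990 to 112577702). It had a peak in 4 of 4 libraries of both pro-B groups and of Mki67-/- small pre-B cells. It had one in 3 of 4 libraries of both pre-pro-B groups and in 0 of 4 of WT small pre-B cells.

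Across the 3 stages, a region 8676 bp from the nearest end of Pwwp2b (chromosome 7, 139275932 to 139276718) had a peak in 12 of 12 Mki67-/- and 0 of 12 WT libraries. A region within Lyrm7 (chromosome 11, 54844002 to 54844960) had one in 12 of 12 WT and 0 of 12 Mki67-/- libraries. Both had a permutation p of 5.83e-06, the smallest possible, and an adjusted p of 0.256. Regions in Dmbt1, Eda2r and near 1700056E22Rik and Ccdc54 were found more often in Mki67-/- libraries, in 11, 9, 8 and 8 of 12 against 0 of 12. Regions nearest Oxa1l, Rmdn2, Pgm2 and Il4ra were found in 12, 12, 12 and 11 of 12 WT libraries and in 1, 1, 1 and 0 of 12 Mki67-/- libraries. Of 87694 regions, 0 passed the adjustment and 1978 had an unadjusted p under 0.05; at least 11 regions at the smallest p would be needed, and 2 had it. Of the 26 regions with p under 0.001, 9 lay on chromosome 7 between 125.6 and 144.4 Mb, 5 on chromosome 11 between 52.5 and 55.4 Mb and 4 on chromosome 1 between 183.9 and 185.4 Mb.

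No gene passed by genotype across stages: of 17594 genes, 0 passed, and 894 had an unadjusted permutation p under 0.05, 202 of them higher and 692 lower in Mki67-/- libraries. Mean coverage was lower in Mki67-/- libraries of each stage, and these deposited lists were not adjusted for it. The smallest p was that of Ccbe1, with means of 6.75 peaks in WT and 5.25 in Mki67-/- libraries (permutation p = 2.33e-05, adjusted p = 0.41). Ntm, which encodes a neural adhesion molecule, had 9.25 and 3.42, and Agbl1 11.8 and 8.5 (adjusted p = 0.445 for both). Nectin4, Ryk, Oxa1l, Mcc, Prep, 4930562C15Rik and Lyrm7 came next on the lower side. Eda2r, Dusp5, Tmprss4, Fat2, Il18bp, Dmbt1, Ppp2r1b, BC049352, Fanci and Rgl2 had the smallest p on the higher side, with adjusted p-values of 0.586. None of the 13 gene lists passed; the lowest p was that of stem and multipotent progenitor genes, with 99.3 ± 19.7 and 92.1 ± 20.5 peaks (n = 12 each, permutation p = 0.0489, adjusted p = 0.408). Among the 40000 strongest peaks this list passed, at 51 ± 7.90 and 46.3 ± 7.24 (n = 12 each, permutation p = 8.75e-05, adjusted p = 0.00114), but not among the 20000 strongest, at 23.3 ± 2.56 and 21.5 ± 2.02 (n = 12 each, permutation adjusted p = 0.398). Early B-lineage genes had 205 ± 33.5 and 199 ± 38.8, and V(D)J recombination genes 75.3 ± 5.94 and 73.8 ± 6.73 (n = 12 each, permutation adjusted p = 0.752 for both).

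Libraries of a genotype resembled each other more than those of the other genotype in pro-B and small pre-B cells. The mean Jaccard index (shared over joint length of peaks) within genotype exceeded that between genotypes by 0.0166 in pro-B and 0.0271 in small pre-B cells, each the highest of 35 splits (exact p = 0.0286). In pre-pro-B cells the difference was 0.00926, and 9 of 35 splits gave as much. The nearest library was of the same stage for 24 of 24 libraries and of the same genotype for 20.

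The next comparison follows the step from pre-pro-B to pro-B cells, in both genotypes together. Early B-lineage genes gained peaks, from 74.4 ± 2.00 to 138 ± 4.49 of the 40000 strongest (n = 8 each, permutation adjusted p = 0.000884). Of its 24 members 17 rose and 0 fell, both over all genes and adjusted over the list alone. Ebf1, which specifies the B lineage, rose from 4.88 ± 1.36 to 17.4 ± 1.60 peaks. Pax5, which commits cells to it, rose from 7 ± 0.756 to 12.8 ± 0.463. Vpreb2, a surrogate light-chain gene, rose from 0 to 4.25 ± 0.463, and Erg from 6.63 ± 0.744 to 14.6 ± 1.06 (n = 8 each).

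T, NK and innate lymphoid genes fell in this step, from 50.1 ± 4.36 to 34.4 ± 2.00 peaks (n = 8 each, permutation adjusted p = 0.000884). Of 20 members 12 fell and 2 rose, over all genes and adjusted over the list alone. Zbtb16, Cd4 and Cd8a fell to 1.5 ± 0.535, 3.13 ± 0.835 and 0, while Tcf7, a factor of T-cell progenitors, rose from 2 ± 0.535 to 7.75 ± 0.886 (n = 8 each). Stem and multipotent progenitor genes fell from 57.5 ± 3.96 to 47.9 ± 2.80 (6 fell and 3 rose of 18, 7 and 3 adjusted over the list alone). Meis1 fell from 9.25 ± 0.886 to 6.25 ± 1.16, Flt3 from 9.5 ± 0.535 to 6.63 ± 0.518 and Hoxa7 from 5.13 ± 0.354 to 3.75 ± 0.463, while Hlf rose from 1.25 ± 0.707 to 2.75 ± 0.463. Myeloid genes fell from 41.5 ± 1.69 to 31.5 ± 2.20 (4 fell and 2 rose of 17 tested, the same counts adjusted over the list alone). Itgam, Csf3r and Elane fell by 3.88, 2.13 and 2 peaks, and Fcgr3 rose by 2.13. In the 20000 strongest peaks the T, NK list had 1.38 and the stem list 0.875 peaks more in pro-B cells, and with gene ends only the stem list had 1 and the myeloid list 1.13 more.

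Other lists rose by less. Cell-cycle genes rose from 68.3 ± 2.66 to 80 ± 2.56, with 6 of 33 up and 1 down over all genes and adjusted over the list alone; Aurkb, a mitotic kinase, rose from 4.25 ± 0.463 to 8.5 ± 0.535, and E2f1, Plk1 and E2f2 rose by 2.38, 1.63 and 2.75. V(D)J recombination genes rose from 43.8 ± 0.886 to 47.1 ± 1.55, with 6 of 18 up and 4 down over all genes and adjusted over the list alone; Rag2 and Lig4 rose by 1.13 and 1 while Xrcc5 and Atm fell by 1.25 and 1. IL-7 signalling genes rose from 79.5 ± 4.14 to 92.3 ± 1.91 (7 of 17 up, 1 down, over all genes and adjusted over the list alone); Socs2, Ccnd3 and Stat5b rose by 5.63, 2.63 and 2.5 and Bcl2 fell by 5.75. Pre-B differentiation genes rose from 100 ± 4.94 to 112 ± 3.07 (9 of 20 up and 3 down, 10 and 5 adjusted over the list alone); Ikzf3, Irf8 and Foxo3 rose by 5.5, 3.13 and 3 and Bach2 fell by 6.75. Mature B-cell genes rose from 50.9 ± 3.04 to 57.6 ± 2.07 (5 of 17 up, 2 down, over all genes and adjusted over the list alone), among them H2-Eb1, Ccr7, Tnfrsf13c and Cxcr5. Plasmacytoid dendritic genes rose from 45.5 ± 2.98 to 49 ± 1.07, although 6 of 13 fell and 3 rose over all genes (7 and 3 adjusted over the list alone); Pacsin1 and Runx2 rose and Klk1 and Cox6a2 fell. Housekeeping genes rose from 52.3 ± 1.39 to 57.1 ± 2.36 (4 of 18 up, 2 down, over all genes and adjusted over the list alone), with Actb, Rpl4 and Hsp90ab1 up.

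Chromatin architecture genes (64.8 ± 2.60 and 67.3 ± 1.83) and erythroid and megakaryocyte genes (26.3 ± 2.05 and 28.3 ± 2.25) did not pass (n = 8 each, permutation adjusted p = 0.0672 and 0.118). Among their members, Nipbl and Stag1 rose and Top2b and Lbr fell, and Pf4, Gp9 and Itga2b rose and Hbb-bt fell. In the deposited lists, which are longer in pre-pro-B cells, the plasmacytoid, chromatin, mature B-cell, IL-7 and pre-B lists turned, to differences of -31.4, -23, -8.88, -6.63 and -5.75 peaks; the first 3 passed in that direction (permutation adjusted p = 0.00318, 0.00354 and 0.00663). In those lists 10 named genes of this step also turned. They were Runx2 (-13.5), Nipbl (-3.63), Stag1 (-3.5), Ikzf3 (-1.13), Foxo3 (-0.875), Itga2b (-0.625), Cxcr5 (-0.375), Hbb-bt (1), Meis1 (1.13) and Hoxa7 (1.25). With the 20000 strongest peaks housekeeping (-2.75) and chromatin genes (-3.25) turned and passed that way (permutation adjusted p = 0.0342 and 0.00862); turned genes were Zbtb16 (0.75), Stat5b (-0.125), E2f1 (-0.5), Plk1 (-0.625), Nipbl (-2), Rpl4 (-0.75) and H2-Eb1 (-0.5). With gene ends only, erythroid genes (-0.625), Erg (-0.5), Stat5b (-0.5) and Bach2 (1.5) turned. Of the 71 genes tested as named in this step, 21 kept their call with gene ends only, 46 with the 20000 strongest peaks and 54 in the deposited lists. Among turned genes, Nipbl, Stag1, Runx2 and Hbb-bt passed the other way in the deposited lists, Nipbl and Zbtb16 with the 20000 strongest peaks and Bach2 with gene ends only.

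**Figure D4:**
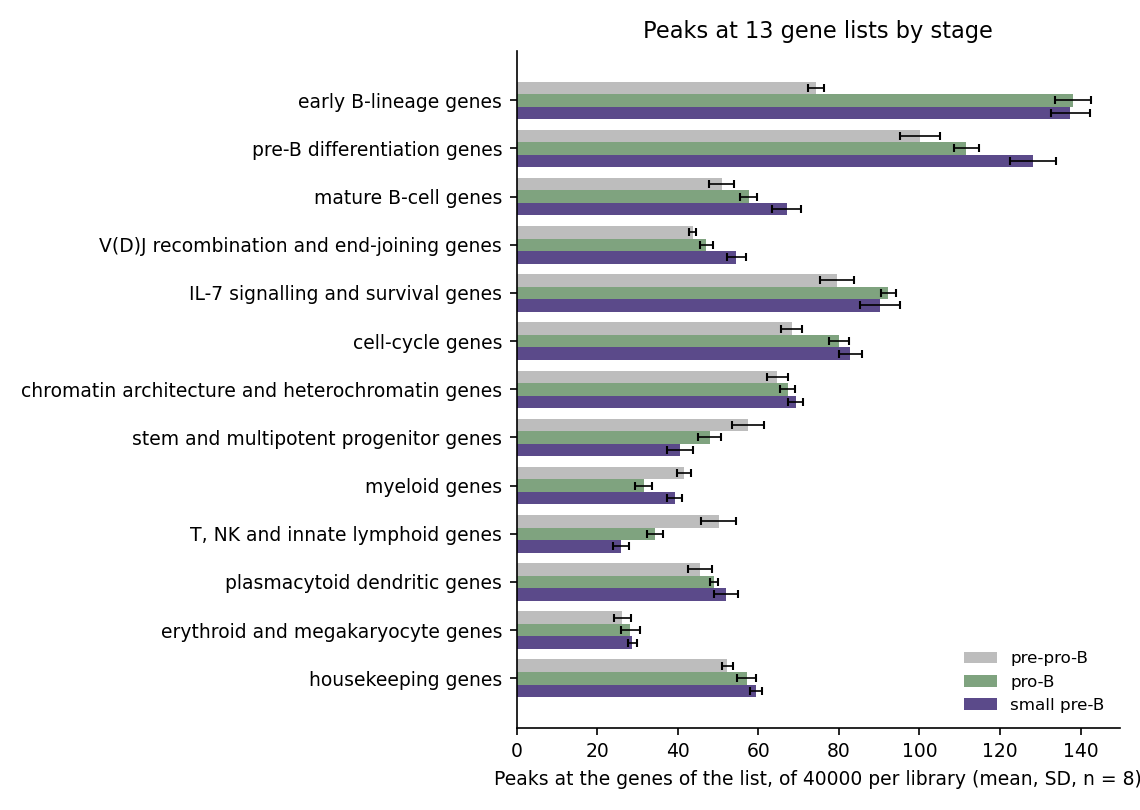
Peaks at the genes of 13 lists among the 40000 strongest peaks per library, as mean and SD by stage (n = 8 libraries, both genotypes). Early B-lineage genes go from 74.4 to 138 peaks between pre-pro-B and pro-B cells and T, NK and innate lymphoid genes from 50.1 to 34.4; with the 20000 strongest peaks the latter differ by 1.38 the other way.

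Over all genes, 4007 rose and 3420 fell of 16213 in this step, and of 39250 regions 12693 were found more often and 14162 less often in pro-B cells. The 10 largest gains at the smallest p were at Slit1 (by 15.3), Gse1, Ebf1, Itga9, Mtss1, Trio, Med13l, Stx8, Epb41l4b and Pde2a (n = 8 each, permutation adjusted p = 0.00164 for each). The 10 largest losses were at Hdac9, a histone deacetylase (17.5 ± 1.77 to 6.25 ± 1.28), Babam2, Frmd4b, Fars2, Gas7, Sdk1, Eepd1, Pard3, Cadm1 and Ppm1h (n = 8 each, permutation adjusted p = 0.00164 for each). With gene ends only, 1349 genes rose and 791 fell, Gse1 had 0.5 fewer and Eepd1 0.25 more peaks; in the deposited lists 28203 regions were lower. Within WT libraries alone, or in blocks by file-name number, no gene passed. Within WT libraries the smallest p is 0.0286, which left almost no room for a call over 16213 genes, and blocks allow few arrangements.

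In this step the Igh locus rose from 36.8 ± 5.68 to 102 ± 8.77 peaks and Igk from 12.8 ± 2.38 to 25.6 ± 3.85, while Igl fell from 6.88 ± 0.354 to 5 (n = 8 each, permutation adjusted p = 0.00049 for each). Tcra/Tcrd (chromosome 14, 52427967 to 54224198) fell from 33.3 ± 3.85 to 15.9 ± 2.03 and Tcrg (chromosome 13, 19178042 to 19352343) from 8.88 ± 0.835 to 3.38 ± 0.744 (n = 8 each, permutation adjusted p = 0.00049 for both). Tcrb (chromosome 6, 40891296 to 41558371) rose from 8.75 ± 1.16 to 10.3 ± 1.04 (n = 8 each, permutation adjusted p = 0.038), but it turned in the deposited lists (-11.3, permutation adjusted p = 0.00204) and with the 20000 strongest peaks (-0.75).

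From pro-B to small pre-B cells the loci changed again. Igk rose from 25.6 ± 3.85 to 156 ± 8.36 peaks and Igl from 5 to 12.5 ± 1.20, and Igh fell from 102 ± 8.77 to 38.4 ± 11.5 (n = 8 each, permutation adjusted p = 0.00049 for each). Tcra/Tcrd fell from 15.9 ± 2.03 to 6.38 ± 1.92 and Tcrb from 10.3 ± 1.04 to 4.25 ± 0.707 (n = 8 each, permutation adjusted p = 0.00049 for both), and Tcrg stayed at a mean of 3.38 (permutation p = 1). With the 20000 strongest peaks 3 loci passed in place of 5.

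Pre-B differentiation genes rose in this step from 112 ± 3.07 to 128 ± 5.72 peaks (n = 8 each, permutation adjusted p = 0.00106), with 7 of 20 up and 1 down over all genes, 9 and 2 adjusted over the list alone. Spib, an Ets factor of B cells, rose from 5.88 ± 0.354 to 8.5 ± 0.926, the chemokine receptor gene Cxcr4 from 3 to 5.5 ± 0.756 and Brwd1 from 3.25 ± 0.463 to 6 ± 1.20 (n = 8 each), while Foxo3 fell by 1.5. Mature B-cell genes rose from 57.6 ± 2.07 to 67 ± 3.70 (n = 8 each, permutation adjusted p = 0.00265), with 4 of 17 up and 0 down over all genes and adjusted over the list alone. Ciita, which drives MHC class II genes, rose by 3.38 peaks, Cd40 by 2.25, Tnfrsf13b by 1.25 and Cd22 by 0.875. T, NK genes fell from 34.4 ± 2.00 to 25.9 ± 1.96 (4 down and 1 up of 15 tested, the same adjusted over the list alone), among them Tcf7, Gata3 and Il2rb. Stem and progenitor genes fell from 47.9 ± 2.80 to 40.5 ± 3.16 (4 of 18 down and 0 up, 4 and 1 adjusted over the list alone), among them Meis1, Hlf, Gata2 and Hoxa7.

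V(D)J recombination genes rose from 47.1 ± 1.55 to 54.5 ± 2.33 (3 of 18 up and 1 down, 4 and 1 adjusted over the list alone), with Polm, Prkdc and Poll up and Paxx down. Myeloid genes rose from 31.5 ± 2.20 to 39.3 ± 1.91 (6 up and 2 down of 15 tested, the same adjusted over the list alone), with Cebpb, Csf1r, Ly6c2 and Csf3r up. Plasmacytoid dendritic genes (49 ± 1.07 to 52 ± 3.07; 4 up and 1 down of 12 tested, 6 and 3 adjusted over the list alone) and housekeeping genes (57.1 ± 2.36 to 59.5 ± 1.51; 2 of 18 up and 0 down, 1 and 0 adjusted over the list alone) also rose (n = 8 each, permutation adjusted p = 0.0298 for both). Among their members Tcf4, Ly6d, Tlr7 and Ywhaz rose and Runx2 fell. In the deposited lists all 4 of these lists turned, to -2.63, -4, -16 and -1.13 peaks. The plasmacytoid one passed that way (permutation adjusted p = 0.0142). Poll (-0.5), Cebpb (-0.375), Tcf4 (-6) and Tlr7 (-0.375) also turned there. Of these genes only Tcf4 passed (permutation adjusted p = 0.0128). With the 20000 strongest peaks myeloid genes (-0.625) and Tcf4 (-0.125) turned, and with gene ends only the myeloid (-0.625), plasmacytoid (-0.625) and housekeeping (-0.375) lists.

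Early B-lineage genes (138 ± 4.49 and 138 ± 4.75), IL-7 signalling genes (92.3 ± 1.91 and 90.1 ± 5.0), cell-cycle genes (80 ± 2.56 and 82.9 ± 2.80), chromatin genes (67.3 ± 1.83 and 69.3 ± 1.91) and erythroid genes (28.3 ± 2.25 and 28.8 ± 1.16) did not pass (n = 8 each, lowest permutation adjusted p = 0.0979). Pax5 fell from 12.8 ± 0.463 to 9.63 ± 1.19 and Vpreb1 from 5.63 ± 0.744 to 3.38 ± 0.518, and Bcl11a and Blk rose by 2.63 and 2.25 (n = 8 each). Plk1, Tyms, Stag2, Lmna and Tal1 fell, and Mcm7, Mcm2, Npm1, Lbr, Bcl2l1 and Nfe2 rose. Turned in the deposited lists were Bcl11a (-0.125), Blk (-0.375), Mcm2 (-0.5), Stag2 (0.25) and Nfe2 (-0.875), and with the 20000 strongest peaks Pax5 (1.38), Tcf7 (0.125), Tnfrsf13b (-0.375), Foxo3 (0.375) and Gata2 (0.125). Early B-lineage genes had 8.13 peaks more with the 20000 strongest peaks (permutation adjusted p = 0.000884), and the cell-cycle (-7.75), chromatin (-10) and erythroid (-12) lists turned in the deposited lists, where the erythroid list passed (permutation adjusted p = 0.00265). Pax5 passed the other way with the 20000 strongest peaks. Of the 64 genes tested as named in this step, 7 kept their call with gene ends only, 34 with the 20000 strongest peaks and 35 in the deposited lists.

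Over all genes, 1799 rose and 1874 fell of 15741, and of 26084 regions 4893 were found more often and 6373 less often in small pre-B cells. The 10 largest gains at the smallest p were at Padi2 (8.25 ± 1.16 to 15.1 ± 1.64), Rreb1, Ago2, Cdkal1, Col26a1, Recql5, Fam53b, Vsir, Cdh23 and Rftn1 (n = 8 each, permutation adjusted p = 0.00468 for each). The 10 largest losses were at Slc39a11, a zinc transporter gene (21.3 ± 0.707 to 11.9 ± 2.80), Snx29, Atxn1, Hivep3, Creb5, Ephb2, Iqgap2, Nfia, Arhgap26 and Dscaml1 (n = 8 each, permutation adjusted p = 0.00468 for each). Hivep3 turned with the 20000 strongest peaks (0.625), and Cdkal1 (-0.5), Rftn1 (-0.125), Snx29 (0.25) and Creb5 (0.375) turned with gene ends only. In the deposited lists 1045 genes rose and 2831 fell. No gene passed in blocks by label or file-name number or within WT libraries alone. With WT libraries the smallest p is 0.0286, which left almost no room for a call over 15741 genes, and blocks allow few arrangements.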

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

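In this part the tests of the Igh pattern were set before their results were seen, and the only comparison chosen after the result was seen is that of chromosome Y entries, for which no test was run.

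In 42 groups of 4 libraries (7 measures in 6 groups), 2 libraries lay far from the other 3, where chance marks about 1 in 20 groups, or 2.1 here. WT pre-pro-B replicate 2 had a mean peak width of 509 bp, against 590 to 605 bp in the other 3. WT small pre-B replicate 1 had 2.44% of its peaks on chromosome X, against 1.95 to 2.01%. In entries that no comparison used, the same library had 33 on chromosome Y, against 18 to 25 in the other 9 libraries read as female from Y-linked genes.

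The genotype effect on Igh peaks differed between stages in the deposited lists. On the log2 scale it was larger by 0.24 in pro-B and by 0.95 in small pre-B than in pre-pro-B cells (permutation adjusted p = 0.0453 and 0.0367). With the 40000 strongest peaks these differences were 0.08 and 0.67 (permutation adjusted p = 0.664 and 0.0722).

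The Igh difference in small pre-B cells was weighed against Igh following the other pro-B regions, those with a peak in all 8 pro-B and none of 8 pre-pro-B libraries. Of 44 such regions in Igh, 51.1% were found in Mki67-/- and 18.8% in WT small pre-B libraries, as a mean over 4 libraries. Regions outside Igh of matched pro-B rank gave 54.0 to 73.3% and 37.5 to 63.1% (95% ranges). Their means were 63.7% in Mki67-/- and 49.7% in WT libraries. Igh lies below both ranges, not within or above. In both genotypes Igh thus kept fewer of its regions than matched regions did, against the prediction of a share within the range. Matched regions were also found more often in Mki67-/- libraries. The gap between genotypes was not itself set against the matched regions, so whether that of Igh exceeds theirs stays open. A biological explanation, Igh that stays open for longer without Ki-67, remains untested.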

How the results depend on the processing

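The tests with a fold enrichment of at least 4, sex as a stratum, coverage as a covariate and without the 3 doubted libraries were chosen after the data were seen. A tested result was taken as unchanged where it kept its direction and side of the threshold. A count without a p-value was taken as unchanged within 1.5 times, or where 0 stayed 0, and otherwise as moved. Of the values that answer a comparison, 208 were unchanged under the alternatives other than leaving out 1 library. Among these values 56 counts moved, 8 results lost their call and 7 turned. Of other results, 674 were unchanged, 545 lost their call, 74 turned, 22 moved and 8 gained a call. Of the 545, 144 came with WT libraries only and 145 with blocks by file-name number, which allow few arrangements. Where no reason is given below, the cause was not tested. Regions and genes by genotype across stages stayed at 0 past the adjustment in all 24 runs without 1 library. Coverage ran from 1.86 to 5.3, so a region missing from a list may have gone unseen in a shallow library; with coverage as a covariate the difference in peak number was 1461 in pre-pro-B and 960 in pro-B cells, and that in covered length 0.658 Mb in small pre-B cells, all turned.

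At a -log10 q of at least 5 the Igh difference across stages was 19.8 (adjusted p = 0.14), and at 10 it was 14.7 (0.407), with 1 locus passing and 514 all-or-none regions in small pre-B cells. With the 40000 strongest peaks all-or-none regions numbered 131 in pre-pro-B and 343 in pro-B cells. Igh in pre-pro-B turned to 3, Igk to 1.5 in pre-pro-B and 0.75 in pro-B cells, and Igk across stages was -1.42 (adjusted p = 0.657); 1 gene list passed by genotype, that of stem and multipotent progenitor genes. With the 20000 strongest, all-or-none regions numbered 55, 246 and 312 in the 3 stages, Igh in pre-pro-B turned to 0.75, Igk to 1.5 in pre-pro-B and 1 in pro-B cells, and Igk across stages was -1.75 (0.436). The regions were then 6660 up and 6906 down in the first step and 3045 up and 3507 down in the second, with 3 loci passing in the second; shorter lists hold fewer regions. With the deposited lists 28203 regions were lower in the first step, and 11368 in the second, where 1045 genes were higher, 2831 lower and 5 lists passed. With bins of 500 bp all-or-none counts were 637, 908 and 1424, and the steps had 24237 and 41948, then 9152 and 13565, since a wide region spans several bins. With gene ends only, the first step had 1349 genes up, 791 down and 7 lists, and the second 287, 401 and 2. With entries not merged the pro-B difference turned to 2441.

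The replicate block pairs libraries by label number, in genotype tests within a stage, so it does not join libraries of the same mouse across stages. With it 1 locus passed by genotype, the Igh difference of 24.6 had an adjusted p of 0.122, and the second step had 2151 regions up, 2355 down and 0 and 0 genes. With blocks by file-name number the first step had 8012 regions up, 8341 down and 0 and 0 genes, and the second 0 and 0 regions, 0 and 0 genes and 0 lists. With WT libraries only, the first step had 0 and 0 genes and the second 0 and 0 regions, 0 and 0 genes and 0 lists. Blocks and fewer libraries allow fewer arrangements, with a smallest p of 0.0078 for 8 pairs and 0.0286 for 4 against 4. At 0.0286 almost no call over all genes was possible. The correlation of libraries of the same label number was -0.18 to 0.0873 within a stage and -0.0253 to 0.0356 within a genotype. For other pairs it was -0.123 to 0.213. These values give no sign of pairing by label number but cannot exclude it. In all pre-pro-B and pro-B groups replicates 1 and 2 were read as female and 3 and 4 as male, so label number follows sex there. In both small pre-B groups only replicate 1 was read as female. With sex as a stratum 1 locus passed and the Igh difference of 24.6 had an adjusted p of 0.066. Without the 3 doubted libraries (Mki67-/- pre-pro-B replicate 4 and replicate 1 of both small pre-B groups), peak number turned to 17.3 in pre-pro-B and 3382 in small pre-B cells and covered length to 1.23 Mb in small pre-B cells; all-or-none regions numbered 404 and 2334 in those stages, 0 loci passed, and Igh was 33.5 (0.0536) and Igk -11.6 (0.0565). Fewer libraries make all-or-none regions more frequent.

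Leaving out each library in turn gave these ranges. Peak number by genotype was -6680 to 17.3 in pre-pro-B and -1678 to 1309 in pro-B cells; covered length was -0.227 to 1.69 Mb in pro-B and -1.93 to 0.34 Mb in small pre-B cells. All-or-none regions were 389 to 841, 672 to 887 and 993 to 1970 in the 3 stages. Across stages 1 to 3 loci passed, and Igh was 19.97 to 30.6, past the threshold in 8 of 24 runs. In the second step early B-lineage genes were -1.70 to 0.357 and erythroid genes -0.107 to 0.893.

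Genes that turned in the first step with the 20000 strongest peaks were Stat5b -0.125, Zbtb16 0.750, E2f1 -0.500 and Plk1 -0.625. Others were Nipbl -2, Rpl4 -0.750 and H2-Eb1 -0.500. The Tcrb locus turned to -0.750. The lists that turned in the first step were chromatin -3.25, stem 0.875, T and NK 1.38, housekeeping -2.75. Genes that turned in the second step with the 20000 strongest peaks were Hivep3 0.625, Tcf7 0.125, Pax5 1.38, Tnfrsf13b -0.375, Tcf4 -0.125, Foxo3 0.375, Gata2 0.125. The lists that turned in the second step were early B-lineage 8.13, myeloid -0.625. Genes that turned in the first step with the deposited lists were Nipbl -3.63, Stag1 -3.50, Hbb-bt 1, Itga2b -0.625, Cxcr5 -0.375, Runx2 -13.5, Ikzf3 -1.13, Foxo3 -0.875, Meis1 1.13. A further gene was Hoxa7 1.25, and the Tcrb locus turned to -11.3. The lists that turned in the first step were pre-B -5.75, mature B-cell -8.88, IL-7 -6.63, chromatin -23, plasmacytoid -31.4. Genes that turned in the second step with the deposited lists were Poll -0.500, Mcm2 -0.500, Stag2 0.250, Bcl11a -0.125, Blk -0.375, Nfe2 -0.875, Cebpb -0.375, Tcf4 -6, Tlr7 -0.375. The lists that turned in the second step were V(D)J -2.63, cell-cycle -7.75, chromatin -10, myeloid -4, plasmacytoid -16, erythroid -12, housekeeping -1.13. Genes that turned in the first step with gene ends only were Gse1 -0.500, Eepd1 0.250, Stat5b -0.500, Erg -0.500, Bach2 1.5. The lists that turned in the first step were stem 1, myeloid 1.13, erythroid -0.625. Genes that turned in the second step with gene ends only were Cdkal1 -0.500, Rftn1 -0.125, Snx29 0.250, Creb5 0.375. The lists that turned in the second step were myeloid -0.625, plasmacytoid -0.625, housekeeping -0.375.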

Other observations

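The placements, the sex balance, the weaker regions near Mki67, the coverage, the pre-pro-B regions and the strongest peaks outside Igh are tests chosen after the result was seen; the others in this part were set before, though the all-or-none splits were read after those counts were seen.

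In the deposited lists, 10454 regions had a peak in all 8 pro-B and none of 8 pre-pro-B libraries, and 13710 the reverse. WT small pre-B libraries had 48.7 to 54.4% of the first set outside Igh and 10.7 to 14.7% of the second. Mki67-/- small pre-B libraries had 47.3 to 77.8% and 5.81 to 10.3%. The first set outside Igh came to 5310 ± 273 regions in WT and 6838 ± 1435 in Mki67-/- small pre-B libraries (n = 4 each, exact p = 0.143). Among the 40000 strongest peaks it came to 3148 ± 221 and 3984 ± 404 (n = 4 each, exact p = 0.0286, the smallest that 4 against 4 allow). In pro-B cells these strongest peaks already held 5910 to 6390 of the regions in WT and 6501 to 6732 in Mki67-/- libraries. A higher count in Mki67-/- libraries is thus not particular to small pre-B cells.

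Other splits of the libraries were counted for each count of regions or genes. Chance is argued against for the all-or-none regions of pro-B cells (526, highest other split 204, 1 of 35). The same holds for small pre-B cells (793, highest other 291, 1 of 35). A share of 1 of 35 is the smallest possible and was not adjusted over the 3 stages. In small pre-B cells 4 of the 8 runs without 1 library gave 2 of 35, each of them without a WT library. Chance cannot be excluded in pre-pro-B cells (263, 6 of 35). The highest other split there, with 643, points to a structure of the samples: its sides had mean coverages of 4.70 and 2.84. By genotype across stages chance is argued against for regions (1978 with p under 0.05, highest other 1321, 1 of 100). It is not for genes (894, highest other 1396, 5 of 100). Between stages, chance is argued against for regions from pre-pro-B to pro-B (26855, highest other 17422, 1 of 100). So it is from pro-B to small pre-B (11266, highest other 0, 1 of 100). For genes both steps argue against it (7427 and 3673, highest other 0, 1 of 100 each).

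Of the 26 regions with p under 0.001 by genotype, 17 lay in 4 windows of 10 Mb, and the highest window, on chromosome 7 with Mki67, held 6. Chance placement is argued against, as 26 regions drawn from all those tested put at most 4 in a window (1 of 1000 placements, the real one included, had as many), and so is the sex of the mice read from Y-linked genes, as the number of female libraries differed by 0 between the genotypes in every stage. A candidate explanation is linked segments that differ between the mouse colonies. The 26 regions prompted it, so it was tested on the 1952 weaker ones (p from 0.001 to 0.05): 3.64% lay within 10 Mb of Mki67, against 1.27% of all tested regions and at most 3.15% in other splits (1 of 100). The groups on chromosomes 11 and 1 are not linked to Mki67 and were not tested for colony differences, and an effect of Ki-67 itself on these segments stays open and untested.

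The higher count of pro-B regions in Mki67-/- small pre-B libraries passes among the 40000 strongest peaks and not in the deposited lists (exact p = 0.0286 and 0.143). A change of Igh alone is argued against by that first p, which is for regions outside Igh. Of the 460 regions of Mki67-/- small pre-B cells 452 lay outside Igh and 8 within it. Of all 10454 pro-B regions 10410 lay outside and 44 within, a smaller share within, so the count of 452 does not bear on this. Longer or deeper lists would also hold more pre-pro-B regions if nothing else differed, but these were fewer (difference -3.82 percentage points, n = 4 each, exact p = 0.0286). Pre-pro-B regions are by definition absent from pro-B libraries, so a state closer to pro-B lowers their share at any list length. Their fall thus cannot decide about longer or deeper lists. Coverage differed by -0.54 (exact p = 0.229), and without the 3 doubted libraries Mki67-/- lists were longer by 3382 peaks. Pro-B cells in the sorted Mki67-/- small pre-B cells are a candidate explanation, with 85.0% of the strongest 20% and 17.9% of the weakest 20% of pro-B regions found in all 4 libraries (ratio 4.75), but WT libraries show the same order (71.0 and 22.4%). The labels give no sort markers that would show whether such cells were removed, and a slower loss of pro-B accessibility without Ki-67 stays open and untested. Among the 40000 strongest peaks, Mki67-/- libraries already had more of the pro-B regions outside Igh at the pro-B stage. Neither explanation was tested against that difference.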
